A study of Drosophila virilis and Drosophila ananassae and Drosophila mojavensis with 56 samples.

How the data were processed

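Small RNA was sequenced from heads, embryos, female bodies and male bodies of up to 11 Drosophila species and from the testis of D. simulans, in 56 libraries. Per the labels, animals were frozen and vortexed, heads were parted from the rest with sieves, and a body sample is the thorax and abdomen. Total RNA was extracted with TRIzol. The labels describe 1 protocol for Illumina GAII libraries, in which RNA of about 18 to 26 nt was ligated to adapters, and 1 for HiSeq libraries, made with a changed TruSeq kit from RNA of 18 to 29 nt, and do not say which library was made by which. The deposited values are raw counts made by the authors, the number of reads of each distinct read sequence in a library, with no normalisation. The tools for adapter removal, and whether reads were matched to a genome, are not given in the sources used here. The reads were 16 to 36 nt long: 37 libraries held nothing outside 18 to 30 nt, and 14 held reads of up to 36 nt.

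Groups were body parts as the labels give them. The first letter of the library identifier (V, M or O) was taken as a library series: heads were 13 V, 5 M and 1 O, embryos 8 V and 8 M, female bodies 11 M, and male bodies 7 V and 2 M. No paired analysis of libraries was possible because the labels pair no library of 1 part with a library of another part. Species entered the fits as a term, and differences in read length were taken within species. Comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives without 7 doubted libraries, with V split in 2 batches, with male bodies for the subgenus, with 2S ribosomal RNA left out of the lengths, and all alternatives of the lists were chosen after seeing the data.

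A read was counted for a miRNA if it was at least 18 nt long and its first 18 bases were those of a listed D. melanogaster mature miRNA. Reads over 30 nt, where a library held them, were counted too. The list of 120 sequences was entered by hand from knowledge of the species and was not checked against a database, so a wrong entry is counted as absent, and miR-2a-3p and miR-2b-3p, which share these bases, were counted as 1. A miRNA whose first 18 bases changed in a species is not counted there, and 4 listed miRNAs were mostly read from another 5 prime end. CPM stands for counts per 1000000 miRNA reads of a library, and RPM for reads per 1000000 reads of the stated length. Mean CPM beside a log2 fold change are of scaled counts. Reads per library ran from 1220335 to 122520026 with a median of 20347500, from 3459842 to 37930995 in embryos, 25652076 to 122520026 in female bodies, 2923577 to 27950394 in heads and 1220335 to 33018440 in male bodies. The testis library had 37936343. A count of 0 was set to a floor of 3 counts over the group where a fold is given. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. 2S ribosomal RNA, a 30 nt RNA of flies, took 6.02% ± 6.82 (SD) of reads in heads, 4.01% ± 4.75 in embryos, 5.10% ± 6.58 in female bodies and 7.85% ± 3.91 in male bodies.

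Counts of 55 libraries, all but the testis, were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr with the design, TMM scaling, quasi-likelihood fits (glmQLFit, glmQLFTest) with part, species and library series as terms, and contrasts of heads against the mean of both bodies, embryos against the mean of the 3 adult parts, and female against male bodies. The standard error is the log2 fold change over the root of the F statistic. Species of the subgenus Drosophila (D. grimshawi, D. mojavensis, D. virilis) and Sophophora were compared in the 11 female bodies, 1 library per species and all of series M, in a fit of their own. Called means a Benjamini-Hochberg adjusted p under 0.05. The miRNAs named were, of those called with a mean of at least 100 CPM and, outside the subgenus comparison, the same sign in at least 0.8 of the species, up to 12 with the largest log2 fold change in each direction; members of lists were named by the size of their change, and in the testis library 5 members by reads. Any other was chosen after its values were seen.

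The 11 lists, written down before the data were examined, were the nervous system, muscle, ovary, testis cluster, digestive and epithelial, Hox cluster, miR-309 cluster, let-7 complex, miR-277 cluster, K-box family and miR-310 cluster lists. They were tested with fry of limma 3.58.1 on log2 CPM from edgeR with a prior count of 2, with adjustment over lists and comparisons. Shares of read lengths, of reads of 18 to 30 nt, were averaged per species and part and compared by exact two-sided sign-flip permutation over species. Whether they differed between the subgenera was tested by exact permutation of the subgenus over species, in 4 tests. Profile similarity used Spearman's rho and 100000 shuffles of part labels within species. Read starts of 18 bases were taken from reads of 20 to 24 nt of female bodies and kept at 50 RPM in at least 1 species, and counted as present at 1 RPM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. A comparison of the testis list with random lists was planned and is not given, since it rests on 1 library and on the members with reads alone.

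The alternatives were relative log expression scaling, DESeq2 1.42.0 (Wald test, same terms), no filter, the whole mature sequence matched, shifted starts (bases 3 to 18 of the miRNA anywhere from the first base of the read to the fifth), no series term, libraries of a species and part summed, limma voom with an estimated correlation within species and part (0.185), series M or V alone, and each species left out in turn. The 7 doubted libraries were the shallowest, a D. pseudoobscura male body; the D. simulans head of series O and the D. simulans female body, both rich in 2S ribosomal RNA; and a head and a male body of D. virilis and both bodies of D. grimshawi, which were led by other sequences. Repeated libraries of a species and part were compared in pairs by chi-square over miRNAs with 20 reads, and the smallest value per degree of freedom was 1248, so none of these pairs held the same library.

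The fits were tested on simulated data in which 10 miRNAs per size (9 in 1 case) were changed by 1, 2 or 3 log2 units. For head against body 3, 7 and 10 were recovered, for embryo against adult 3, 9 and 10, for female against male body 0, 7 and 8, and for the subgenus 1, 7 and 9. False calls among the unchanged were 1 of 75, 2 of 75, 0 of 74 and 1 of 68. All simulated libraries had 1 mean profile, with no effect of species or library series and no correlation between repeated libraries. The false calls therefore say nothing of errors that such effects bring into the real fits. Reads outside 18 to 30 nt were not analysed here, except that miRNA counts took in longer reads. The unlisted reads beyond their starts were not analysed either.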

Results

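The 56 small RNA libraries came from 11 Drosophila species and held 1349950128 deposited reads, from 1220335 in a D. pseudoobscura male body library to 122520026 in the D. pseudoobscura female body library. Heads gave 19 libraries from 10 species, embryos 16 from 10 species, female bodies 11 from 11 species, male bodies 9 from 7 species, and the testis of D. simulans gave 1. A body is the thorax and abdomen left after the head was removed. Reads of at least 18 nt that began with the first 18 bases of a listed D. melanogaster miRNA came to 46.9% ± 13.9 (SD, n = 19) of the number of reads of 18 to 30 nt in heads, 27.3% ± 16.2 (n = 16) in embryos, 21.1% ± 9.85 (n = 11) in female bodies and 15.5% ± 6.37 (n = 9) in male bodies. Of the listed miRNAs 8 had no read in any library, 15 reached 10 counts per 1000000 miRNA reads (CPM) in none and 80 reached that level in a library of every species. The list was entered by hand and was not checked against a database, and a wrong entry would give 0 reads, so a miRNA without reads, or a list with few members found, is not shown to be absent. All 11 members of the digestive and epithelial list, all 5 of the Hox cluster list, all 3 of the miR-277 cluster and both muscle miRNAs reached that level in every species, as did 14 of 17 of the nervous system list, 6 of 7 of the ovary list, 5 of 6 of the K-box family and 2 of 3 of the let-7 complex. The miR-309 cluster did so for 1 of 6 members, the miR-310 cluster for 0 of 4 and the testis cluster list for 0 of 18. Of the miR-309 cluster, miR-3-3p, miR-4-3p, miR-5-5p and miR-6-3p missed it only in D. grimshawi (0.598, 2.99, 5.38 and 9.56 CPM), which had no embryo library. Testis was sampled in 1 species alone, so these counts also depend on the parts sampled. The labels do not say that the libraries of a group come from separate cultures, so p-values measure the spread between these libraries and species, and related species are not independent of each other.

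Libraries carry a series letter, V, M or O, and the letter moved the counts of many miRNAs. With body part and species held fixed, 67 of 107 miRNAs differed between series V and M in edgeR, 28 higher in V and 39 higher in M. miR-276a-5p was 7.48 log2 units and miR-980-3p 5.48 higher in V, whereas miR-92b-3p was at -5.23 and miR-190-5p at -4.97. All 11 female bodies were of series M and 7 of the 9 male bodies of series V, so each comparison had the series as a term and was repeated among libraries of series M alone. Values after ± are standard errors of the fit unless marked SD, and tests were two-sided with Benjamini-Hochberg adjustment over the 107 miRNAs of a comparison.

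Heads were set apart from bodies by miRNAs of the nervous system. miR-315-5p, known as an activator of Wingless signalling, was 141-fold higher in heads (7.14 ± 0.50 on the log2 scale, adjusted p 8.5e-17; mean 6459 CPM in heads). miR-285-3p, which shares its seed with vertebrate miR-29, rose by 7.07 ± 0.56 (7.27 ± 1.22 within series M and 6.92 ± 0.70 within V), and miR-210-3p, which is expressed in photoreceptors, by 5.90 ± 0.51 (5.63 ± 0.98 and 5.27 ± 0.74). miR-1000-5p, a regulator of glutamate loading in neurons, rose by 3.84 ± 0.32. miR-124-3p, the most studied neuronal miRNA of animals, was 14.2-fold higher (3.82 ± 0.49, 3.2e-09; means of 13381 and 308 CPM), at 5.03 ± 0.48 within series V and 2.68 ± 0.91 within M. In series M 4 of 5 heads held at most 186 CPM of it, fewer than the female body in D. virilis (436), D. willistoni (407) and D. yakuba (464), and the D. pseudoobscura head held 2928, so within M its lead over bodies rests on that head and on low male bodies. miR-276b-3p, a sister of the miR-276a that acts in olfactory memory, was 6.12 ± 0.35 higher. Each of these 6 was higher in heads in 10 of 10 species over all libraries of a species. The bodies were led by miR-989-3p, an ovarian miRNA needed for border cell migration, which was at -7.97 ± 0.67 in heads (165 against 6792 CPM), and by miR-314-3p at -6.87 ± 0.50. miR-281-3p, of the digestive and epithelial list, was at -5.51 ± 0.33 (2.8e-19), and miR-375-3p, whose vertebrate counterpart acts in pancreatic islets, at -4.09 ± 0.35. miR-1-3p, the muscle miRNA of animals, was at -3.75 ± 0.82.

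For head against body, 71 of 107 miRNAs passed an adjusted p of 0.05 across 19 head and 20 body libraries, 31 higher and 40 lower in heads. Of these, 51 had the same sign in at least 0.8 of the 10 species, and 9 had the sign of the minority of species. In 10 the means over all libraries went against the fit, among them miR-34-5p and miR-14-3p. Within series M, 39 of 104 passed, all of them among the 71, and 69 of 70 kept their sign. The 24 miRNAs named by the rule kept their call in 21 cases there. The exceptions were miR-958-3p, at -4.78 ± 2.01 in series M, miR-1-3p at -3.40 ± 2.04 and miR-318-3p at -1.91 ± 1.69. Within series V, where all bodies are male, miR-92a-3p was at -0.28 ± 0.74 against -4.47 ± 0.56 in the joint fit, and miR-318-3p at -1.15 (0.320), so that miR-318-3p was called in neither series alone. Leaving out 1 species changed the fold of 6 named miRNAs by over 1.5 times and ended no call: without D. ananassae miR-193-3p, at 6.06 ± 0.64 in all libraries, was at 7.74, without D. pseudoobscura miR-958-3p was at -6.58 against -5.48 ± 0.79 and miR-1-3p at -4.65, without D. willistoni miR-987-5p was at 3.97 against 4.62 ± 0.59, without D. virilis miR-318-3p was at -3.77 against -3.10 ± 0.89, and miR-994-5p, at -5.64 ± 0.83, was at -5.04 without D. mojavensis and -6.38 without D. virilis. Without 7 doubted libraries, 70 passed, 31 higher and 39 lower.

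Lists of miRNAs fixed before the data were examined were tested with fry, which asks whether the members of a set move one way on balance and does not compare the set with others. The 43 tests over 4 comparisons formed 1 family. In heads, 13 of 16 tested members of the nervous system list rose, 2 fell (miR-958-3p and miR-87-3p at -1.25 ± 0.35) and miR-7-5p was at 0.24 ± 0.79 (fry adjusted p 1.53e-16). In the ovary list 5 of 7 fell, led by miR-989-3p and miR-994-5p, while miR-9c-5p and miR-306-5p did not pass (1.53e-11). The Hox cluster list had 4 of 5 lower, miR-iab-8-5p most at -4.24 ± 0.61, a miRNA of the bithorax complex, and miR-993-3p at 0.29 ± 0.37 (6.21e-11). In the digestive and epithelial list 6 of 11 fell, 1 rose (miR-14-3p, 1.15 ± 0.38) and 4 did not pass (5.81e-10). The miR-310 cluster, a fast-evolving cluster related to miR-92, had 3 of 4 lower (2.01e-04, and 0.135 in series M), and the testis cluster list 4 of 8, led by miR-962-5p at -5.33 ± 0.72 (0.0152, and 0.172 in series M). Of the testis list, miR-963-5p and miR-977-3p were called lower but had higher means in heads (0.733 against 0.268 and 1.51 against 0.345 CPM). Each had the fitted sign in 4 of 10 species. The other lists did not pass. In the muscle list miR-133-3p rose (3.12 ± 0.36) and miR-1-3p fell, and fry gave the direction up although median and mean were -0.32 (0.181, and up at 0.00187 without the series term). In the miR-277 cluster miR-317-3p rose (2.01 ± 0.55) and miR-34-5p fell (-1.61 ± 0.36; 0.143, and down at 0.0195 with relative log expression scaling, 0.0400 without a filter and 5.63e-04 with the whole sequence matched). In the let-7 complex 1 of 3 rose (miR-125-5p, 1.25 ± 0.37; 0.342). miR-13a-3p (3.09 ± 0.55) rose and miR-6-3p fell in the K-box family of 6 (0.249), and 2 of 6 fell in the miR-309 cluster (0.222). Counts adjusted over the list alone were the same except in the miR-309 cluster, where 1 fell.

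**Figure D1:**
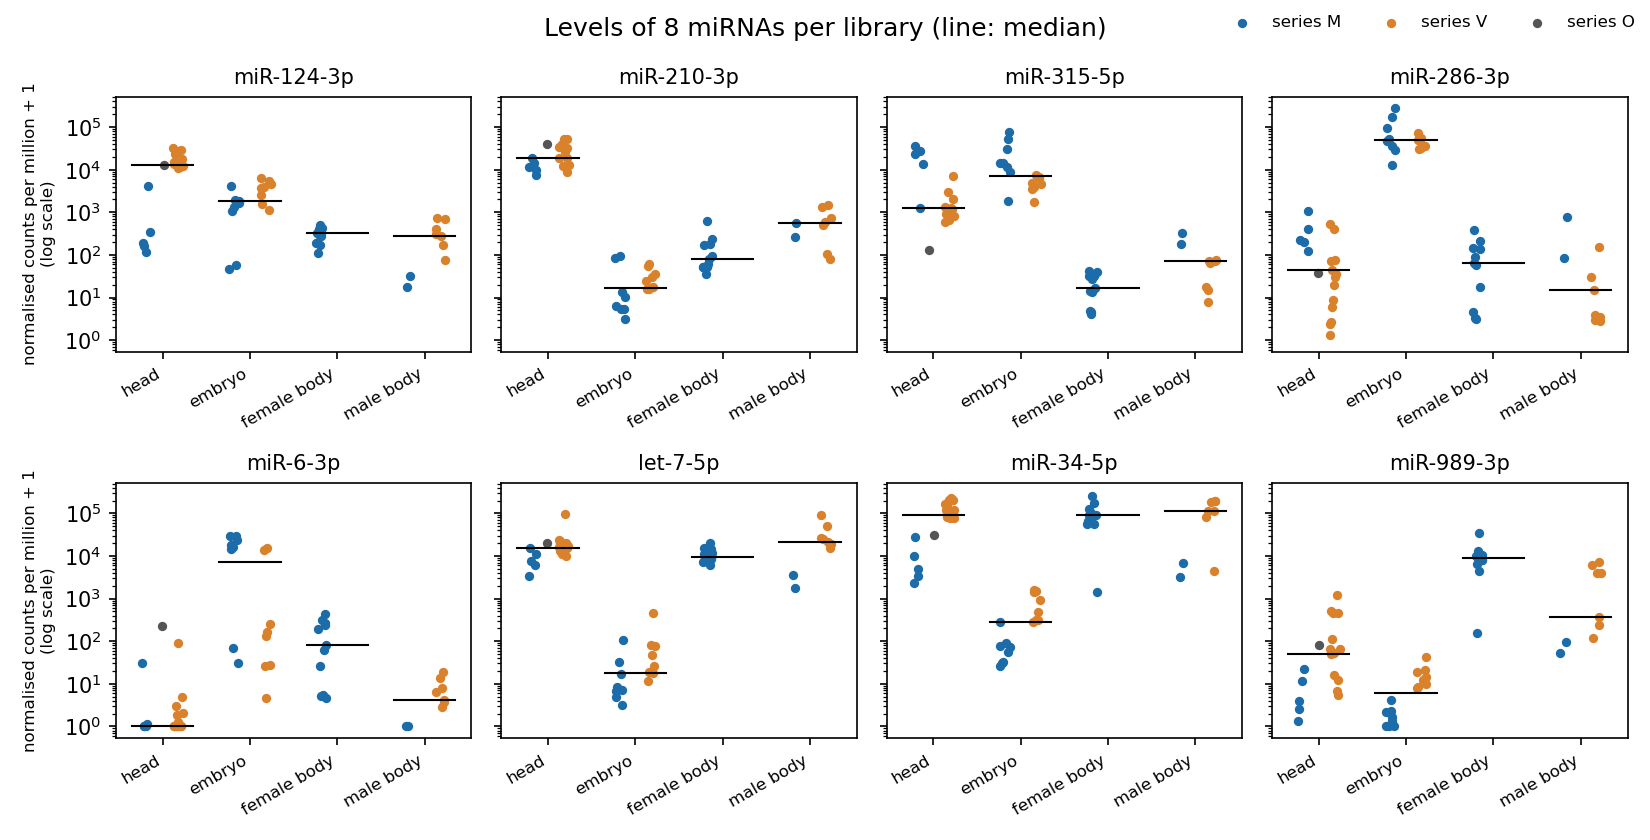
Normalised CPM plus 1 (log axis) of 8 miRNAs in each library of heads (n = 19), embryos (n = 16), female bodies (n = 11) and male bodies (n = 9); points are libraries coloured by series letter, and lines are medians. By medians heads stand above bodies for miR-124-3p (3.82 in the fit, log2; heads reach down to 117.3 CPM, below the female body median of 319) and miR-210-3p (5.90), embryos above adult parts for miR-286-3p (10.01) and miR-6-3p (9.03), and embryos below them for let-7-5p (-9.01) and miR-34-5p (-8.34).

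Embryos were marked by the miR-309 cluster, which clears maternal messenger RNAs at the start of zygotic transcription. miR-286-3p was 1034-fold higher than in adult parts (10.01 ± 0.84, adjusted p 1.3e-14), with means of 69378 and 139.9 CPM. miR-4-3p (9.25 ± 0.87), miR-6-3p (9.03 ± 1.17), miR-5-5p (8.32 ± 0.56), miR-3-3p (6.62 ± 0.49) and miR-309-3p (4.61 ± 0.88) rose with it. miR-92a-3p (5.08 ± 0.44) and miR-92b-3p (5.24 ± 0.58), which act in neuroblasts, were also higher in embryos, as were miR-315-5p (6.05 ± 0.38) and miR-312-3p of the miR-310 cluster (4.45 ± 0.64). The adult parts were marked by the let-7 complex, which acts in the passage from larva to adult: let-7-5p was at -9.01 ± 0.55 in embryos (2.5e-19; 56.6 against 18734.5 CPM), miR-125-5p at -7.88 ± 0.44 and miR-100-5p at -6.12 ± 0.60. miR-34-5p, which protects the ageing brain, was at -8.34 ± 0.45 (8.8e-21), and its cluster partners miR-317-3p and miR-277-3p, the last a regulator of branched-chain amino acid breakdown, at -5.51 ± 0.57 and -4.83 ± 0.36. miR-210-3p (-5.85 ± 0.50) and miR-278-3p (-5.34 ± 0.44), which acts in energy balance, were lower in embryos too.

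For embryo against adult, 82 of 107 passed across 16 embryo and 39 adult libraries, 43 higher and 39 lower in embryos. In 67 the sign was the same in at least 0.8 of the 10 species, and 0 had a minority sign, while in 5 the means over all libraries went against the fit, among them miR-124-3p (2577 CPM in embryos and 6677 in adults, of which heads hold most). Within series M 63 of 104 passed, 57 of them among the 82, and 76 of 80 kept their sign, and within series V 75 passed. Of the 24 named, 23 were called in series M, where miR-311-3p was at 1.21 ± 1.45 against 3.79 ± 0.81 jointly. Omitting 1 species ended no named call and moved the fold of 7 by over 1.5 times: miR-312-3p was at 3.75 without D. ananassae and 3.73 without D. persimilis, miR-286-3p at 9.41 without D. mojavensis, miR-6-3p at 9.63 without D. persimilis and 7.83 without D. willistoni, miR-968-5p, at 6.24 in all libraries, at 7.27 without D. persimilis and 5.56 without D. yakuba, miR-318-3p at -6.75 without D. persimilis against -5.87 ± 0.94, miR-278-3p at -5.95 without D. sechellia, and miR-311-3p at 2.95 without D. yakuba. Without the 7 doubted libraries 85 passed, 35 higher and 50 lower, so the balance of directions turned from 52.4% to 41.2% higher in embryos. Scaling by relative log expression in place of TMM shifted the median log2 fold change by -0.11, -0.13, -0.13 and -0.10 in the comparisons of head and body, embryo and adult, female and male body, and subgenus.

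All 6 tested members of the miR-309 cluster rose in embryos (fry adjusted p 1.62e-18), and all 3 of the let-7 complex (2.45e-28) and all 3 of the miR-277 cluster (2.25e-28) fell. In the K-box family, whose seed pairs with the K box of Notch target messages, 5 of 6 rose and miR-11-3p was at 0.36 ± 0.19 (1.14e-08). All 4 of the miR-310 cluster rose in the fit (2.89e-06, and 0.0617 in series M), and 3 of 5 of the Hox cluster list, led by miR-iab-4-5p at 5.45 ± 0.43 (5.94e-10). By its means miR-310-3p was lower in embryos (24.4 against 81.2 CPM), and it had the fitted sign in 5 of 10 species. In the ovary list miR-989-3p (-7.85 ± 0.67), miR-994-5p and miR-318-3p fell and 3 rose, so that the median was 0.05, the mean -2.25 and the direction of fry down (2.27e-06). In the digestive and epithelial list 7 of 11 fell, miR-278-3p and miR-281-3p (-2.69 ± 0.28) most (5.96e-10), and in the testis cluster list 3 of 8 fell, led by miR-964-5p at -3.65 ± 0.67 (0.0150, and 0.376 in series M). The nervous system list split into 8 higher, among them miR-315-5p and miR-124-3p (1.40 ± 0.39), and 6 lower, among them miR-210-3p and miR-285-3p (-5.09 ± 0.51; 0.954). It moved down without the doubted libraries (1.09e-04). In the muscle list miR-133-3p fell (-0.78 ± 0.31) and miR-1-3p was at -0.55 ± 0.75 (0.0549, but 0.0181 with relative log expression scaling, 0.0461 without a filter and 1.01e-04 without the doubted libraries). Counts adjusted over the list alone did not differ.

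miRNAs of the ovary list were among those higher in female than in male bodies. miR-989-3p was 122-fold higher in females (6.93 ± 0.95, adjusted p 7.8e-08), with means of 10301 and 2503 CPM, and was at 7.31 ± 1.41 within series M. miR-994-5p, transcribed with miR-318, was at 6.01 (adjusted p 3.0e-05; 5.78 ± 2.06 in series M), and miR-318-3p, a miRNA of ovarian follicle cells, at 3.95 ± 1.30 (3.08 ± 2.32, not called in series M). miR-92a-3p (5.20 ± 0.84) and miR-965-3p (6.07 ± 1.07) were higher in females within series M too (3.75 ± 1.43 and 11.53 ± 2.90). miR-125-5p was at 4.26 ± 0.58. Among miRNAs higher in males miR-281-5p stood out, at -5.85 ± 0.77 for females over males (4.5e-08; 4262 against 63155 CPM), whereas the other arm, miR-281-3p, was at 1.43 ± 0.47. A D. virilis male body library with 366279 CPM of miR-281-5p carried that mean: the other male bodies held 5323 to 119278, with a mean of 25264. The 119278 was of D. pseudoobscura M022, so the highest males were those of series M. For V over M miR-281-5p was at -3.96 ± 0.51 and miR-281-3p at 1.74 ± 0.32. Without D. virilis the value of miR-281-5p between the sexes was -5.38, and without the series term -2.68. miR-263a-5p, which protects bristle progenitors from cell death, was at -3.10 ± 0.55, miR-8-3p, the fly member of the miR-200 family, at -2.58 ± 0.42, miR-10-5p of the Hox cluster at -3.02 ± 0.54, and bantam-3p, a promoter of tissue growth, at -2.28 ± 0.49 (-1.04 ± 0.61, not called in series M). miR-964-5p, of a testis cluster, was at -4.14 ± 0.93 (10.1 against 313 CPM; -3.84 ± 1.79, not called in series M). miR-310-3p had 437 reads in female and 1 in male bodies of the 7 species with both, a raw log2 ratio of 7.62 (95% counting interval 5.13 to 12.92). Another 21298 reads came from female bodies of species without a male library, where D. simulans held 1667 CPM and D. sechellia 1445, and say nothing of the sexes. The fitted value of 5.11 ± 1.72 depends on the prior count and turned to -1.40 ± 3.39 in series M.

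For female against male body, 69 of 107 passed across 11 female and 9 male libraries, 46 higher and 23 lower in females. Of these, 47 had the same sign in at least 0.8 of the 7 species with both sexes, and 9 had the sign of the minority of species. In 5 the means went against the fit, among them miR-276a-5p and miR-1-3p. Series M holds 2 male libraries, of D. pseudoobscura and D. virilis, whose identifiers lie apart from those of the female bodies. There 47 of 104 passed, 26 higher and 21 lower, 39 of them among the 69, 63 of 68 kept their sign, and 18 of the 24 named miRNAs were called. The other 6 were miR-310-3p, miR-125-5p at 2.97 (adjusted p 0.0627), miR-318-3p (0.292), miR-282-5p at 2.65 (0.120), miR-964-5p (0.0936) and bantam-3p (0.177). bantam-3p also lost its call with V split in 2 batches (-0.95, 0.0622), and miR-310-3p did with that split (3.24, 0.148), with DESeq2 (2.98, 0.0661) and with limma voom (2.07, 0.122). Without the series term 59 passed, and miR-989-3p was at 2.16 (0.0879), miR-375-3p at -0.67 (0.303) against -2.80 ± 0.51 and miR-999-3p at -1.16 (0.0646) against -2.61 ± 0.52. Without the 7 doubted libraries 63 passed, 36 higher and 27 lower, and miR-958-3p went from 4.46 ± 1.23 to 2.14 (0.121). When the whole mature sequence had to match, miR-282-5p went from 3.78 ± 0.75 to 1.16 (0.274). Leaving out 1 species moved the fold of 16 named miRNAs by over 1.5 times and ended no call. Without D. virilis, miR-989-3p was at 6.29, miR-965-3p at 5.36, miR-994-5p at 5.02, miR-92a-3p at 7.19, miR-310-3p at 8.12, miR-125-5p at 5.17, miR-318-3p at 3.17 (0.0420) and miR-263a-5p at -2.48. Without D. willistoni, miR-989-3p was at 7.58, miR-994-5p at 6.92, miR-310-3p at 4.51, miR-318-3p at 4.65 and miR-314-3p at 4.53. Without D. mojavensis miR-994-5p was at 6.76 and miR-318-3p at 4.57, without D. simulans miR-281-5p at -5.10, miR-987-5p at -2.37, miR-31b-5p at -2.11 and miR-31a-5p at -1.48, without D. yakuba miR-964-5p at -3.12, without D. pseudoobscura miR-957-3p at -4.50, without D. persimilis miR-958-3p at 3.87 and miR-987-5p at -2.32, and without D. erecta miR-958-3p at 5.09.

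In the ovary list 6 of 7 rose in female bodies and miR-9c-5p was at -0.44 ± 0.73 (fry adjusted p 5.12e-10, and 0.00375 in series M). In the testis cluster list 4 of 8 fell, led by miR-959-3p at -5.89 ± 1.17 (0.00238, and 0.284 in series M). In the let-7 complex miR-100-5p and miR-125-5p rose and let-7-5p was at 0.38 ± 0.67 (2.20e-06, and 0.0617 in series M), and in the miR-277 cluster miR-277-3p and miR-34-5p rose, although mean levels of miR-34-5p were 100823 and 99505 CPM, so its 3.73 ± 0.60 rests on the series term, and miR-317-3p was at -1.02 ± 0.70 (6.27e-05, and 0.589 in series M). The miR-310 cluster had 3 of 4 higher, and 4 when adjusted over the list alone (0.00257, and 0.320 in series M). The K-box family had 3 of 6 higher, led by miR-13a-3p at 2.93 ± 0.94, and 4 higher with 1 lower when adjusted over the list alone (8.79e-04, 0.110 in series M and 0.203 without the doubted libraries). Of those higher, miR-2a/2b-3p (1.63 ± 0.53) had a lower mean in females (19446 against 34298 CPM) and the fitted sign in 2 of 7 species. In the nervous system list 6 rose, led by miR-219-5p at 5.53 ± 0.65, miR-315-5p fell (-4.22 ± 0.61) and 9 did not pass (0.00162, and 0.203 without the doubted libraries). miR-1-3p of the muscle list was at 3.44 ± 1.39 in the fit, with that sign in 2 of 7 species, and miR-133-3p at -0.60 ± 0.55 (0.0150, 0.828 without the series term and 0.726 without the doubted libraries). In the digestive and epithelial list 6 fell, led by miR-281-5p and miR-263a-5p, and 3 rose, led by miR-14-3p at 3.78 ± 0.65 (0.0645, but 2.60e-05 with relative log expression scaling, 0.0475 in series M and 5.46e-04 without the doubted libraries). In the Hox cluster list 3 fell and miR-iab-4-5p rose (4.39 ± 0.78); fry gave the direction down (0.228, but 2.63e-04 with relative log expression scaling, 0.00554 with the whole sequence matched, 0.0475 in series M and 0.0411 without the doubted libraries) and, without the series term, up (0.0166). In the miR-309 cluster 2 of 6 rose, miR-4-3p most at 3.98 ± 1.51 (0.228). Counts adjusted over the list alone did not differ in the lists for which none is given.

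**Figure D2:**
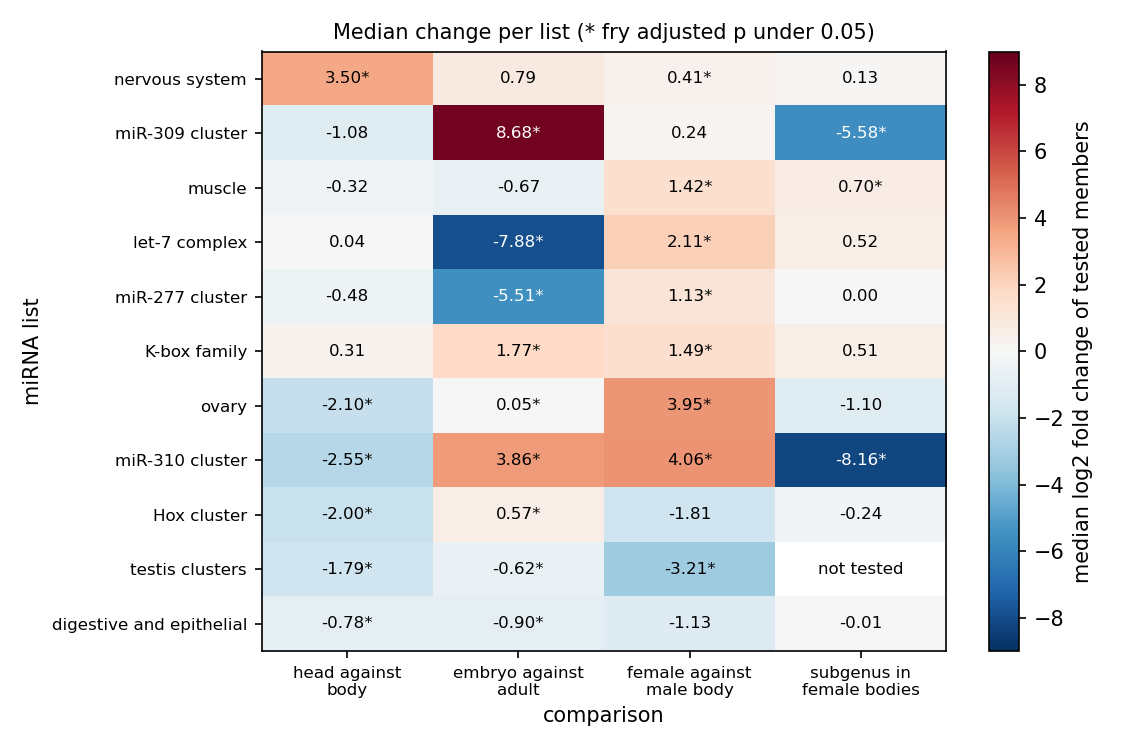
Median log2 fold change of the tested members of 11 miRNA lists (vertical axis) in 4 comparisons (horizontal axis), as colour and number; a star marks a fry adjusted p under 0.05. The medians are of fitted values: with members read 0 to 3 times in a group set to their raw ratio or bound, the miR-310 cluster in females against males moves from 4.06 to 3.67 (ratios over the 7 species with both sexes) and the miR-309 cluster in the subgenus comparison from -5.58 to -5.45, and relative log expression scaling shifts medians by -0.10 to -0.13.

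Among female bodies, D. grimshawi, D. mojavensis and D. virilis of the subgenus Drosophila were set against 8 species of the subgenus Sophophora, and members of the miR-309 and miR-310 clusters were lower in the first. miR-6-3p was at -5.61 ± 0.97 (adjusted p 0.00135; 4.18 against 201 CPM), and miR-286-3p, chosen with the other members of its cluster after their values were seen, at -5.55 ± 0.96 (2.88 against 129). miR-309-3p had 0 reads in the 3 species and 312 in the 8, at least 41.1-fold lower with 3 counts over the group as the floor, and did not pass (0.0997). It reached 1 CPM in only 3 of the 8. In embryos it was at 0.577 CPM in D. mojavensis and 0.245 in D. virilis against a mean of 278 in Sophophora, so a changed sequence is not excluded for it. miR-311-3p was at -8.64 ± 2.17 (1.42 against 544) and miR-312-3p at -8.21 ± 1.99 (2.69 against 771). miR-986-5p, with the largest fold of the named miRNAs, was at -8.71 ± 1.48 (0.00135; 1.67 against 692). miR-998-3p, encoded in an intron of E2f1, was higher at 2.45 ± 0.59, and miR-282-5p at 4.13 ± 0.71. A counted read must begin with the D. melanogaster sequence, so a changed base removes a miRNA from the count. In embryos miR-286-3p reached 82594 CPM in D. mojavensis and 45266 in D. virilis against a mean of 77960 in Sophophora, whereas miR-311-3p reached 2.41 and 2.36 against 1432 and miR-986-5p 1.41 and 0 against 1142 (highest in any library 41.7 in D. willistoni, of Sophophora, and 116.3 in D. virilis). The Sophophora mean of miR-311-3p came mostly from 4 of the 8 species: its highest level in any library was 9109 CPM in D. simulans, 4341 in D. yakuba, 1527 in D. sechellia and 1099 in D. erecta, but 67.2 in D. ananassae, 55.96 in D. willistoni, 20.7 in D. persimilis and 11.7 in D. pseudoobscura, near the 33.5 of D. virilis. The highest level of miR-312-3p was likewise 48.9 in D. willistoni and 38.1 in D. pseudoobscura, against 40.3 in D. mojavensis.

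For the subgenus in female bodies, edgeR called 14 of 98 miRNAs, 3 higher and 11 lower in subgenus Drosophila, with 29 at an unadjusted p under 0.05, and DESeq2 called 20. The count was 7 without D. grimshawi, 7 without D. virilis, 9 without D. mojavensis, 8 without the doubted libraries and 4 among the 83 miRNAs with 10 reads in each library. Only miR-986-5p and miR-6-3p of the 8 named kept their call when each of the 11 species was left out. Without D. grimshawi, miR-282-5p was at 1.22 and miR-998-3p at 1.75 (both 0.137), miR-311-3p at -8.89 (0.0603), miR-312-3p at -8.56 (0.0594), miR-10-5p at -1.28 (0.117) against -1.23 ± 0.38 in all libraries, and miR-281-3p at -1.04 (0.137) against -1.08 ± 0.34. Without D. virilis miR-311-3p was at -8.69 (0.0881), miR-312-3p at -8.27 (0.0809), miR-10-5p at -0.90 (0.179) and miR-281-3p at -1.22 (0.0940), and without D. mojavensis miR-311-3p was at -8.32 (0.0673), miR-312-3p at -7.89 (0.0641) and miR-281-3p at -0.98 (0.147). miR-10-5p also lost its call without D. erecta (0.0724), D. pseudoobscura (0.0666), D. sechellia (0.0755) or D. willistoni (0.0648), and miR-281-3p without D. erecta (0.0710), D. persimilis (0.0762), D. pseudoobscura (0.0666), D. sechellia (0.0755) or D. simulans (0.0652). miR-312-3p was at -7.61 without D. yakuba. When the whole mature sequence had to match, miR-282-5p was at 0.85 (0.538), and miR-10-5p (-1.51, 0.0820) and miR-281-3p (-1.13, 0.135) lost their calls. miR-281-3p also lost it with relative log expression scaling (-1.18, 0.0518), and both did with 10 reads required in each library (-1.24, 0.0926 and -1.11, 0.127). Where matching, scaling or the read limit ended a call of miR-10-5p or miR-281-3p, the fold was at least as large as in all libraries. That of miR-282-5p with the whole sequence matched was smaller. Without the doubted libraries 6 of the 8 were not called: miR-282-5p (1.38, 0.0567), miR-998-3p (1.84, 0.108), miR-311-3p (-8.65, 0.0905), miR-312-3p (-8.39, 0.0791), miR-10-5p (0.156) and miR-281-3p (-0.79, 0.220). Of these miR-311-3p and miR-312-3p kept their fold, and the others had a smaller one. In heads edgeR called 0 of 102 miRNAs, with 3 at an unadjusted p under 0.05 and 0 by DESeq2, and in male bodies 0 of 89, with 7 and 1. The differences between parts were not tested.

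In the miR-309 cluster 5 of 6 were lower in subgenus Drosophila, and 6 when adjusted over the list alone (fry adjusted p 2.64e-04). In the miR-310 cluster 2 of 4 were lower (0.0480, 0.203 without the doubted libraries and 0.0580 with shifted starts allowed). The muscle list passed with 0 of 2 members called (0.0488, but 0.130 without a filter, 0.0875 with the whole sequence matched and 0.163 without the doubted libraries): edgeR put miR-1-3p at 0.96 ± 0.42 and miR-133-3p at 0.44 ± 0.35. miR-10-5p was the 1 member of 5 lower in the Hox cluster list (0.296) and miR-6-3p the 1 of 6 in the K-box family, whose median was 0.51, mean -0.38 and fry direction up (0.771). In the digestive and epithelial list 1 of 11 fell, and 2 when adjusted over the list alone (0.266). The nervous system list (0.452), the let-7 complex (0.248), the miR-277 cluster (0.270) and the ovary list (0.173) had 0 called in edgeR. The testis cluster list had 1 tested member and was not tested.

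**Figure D3:**
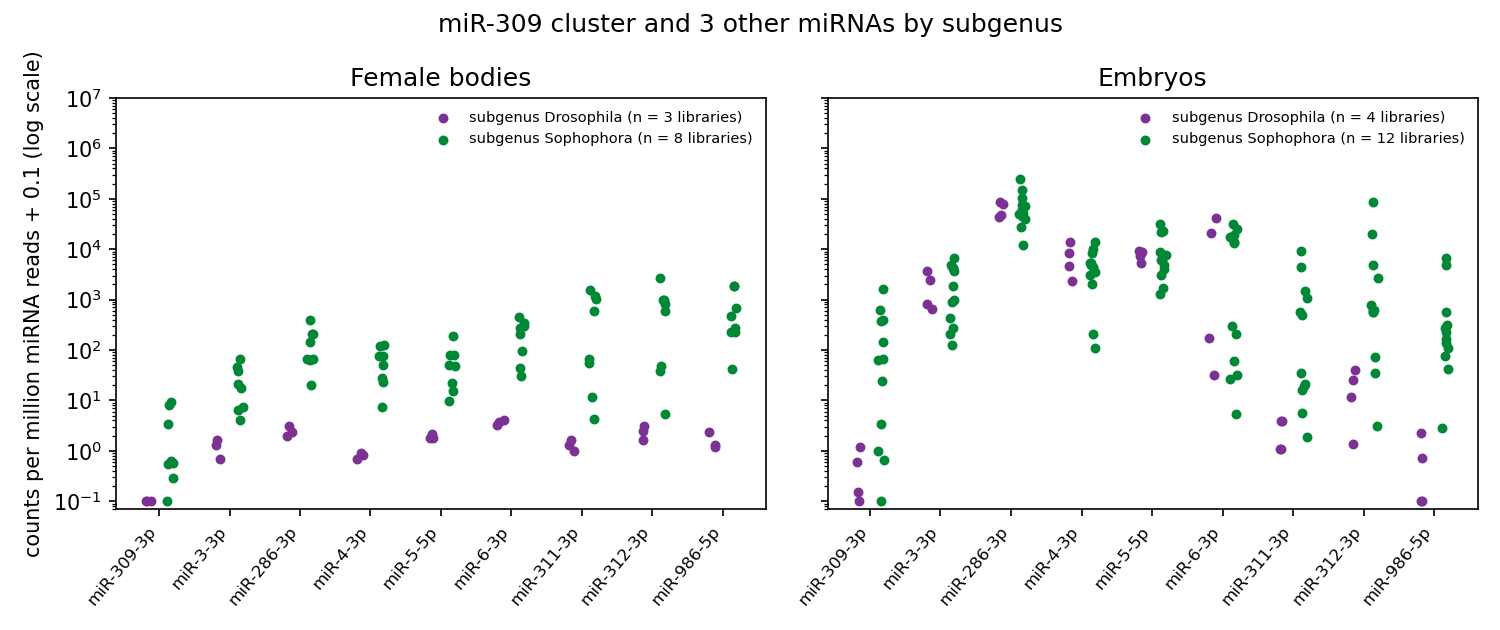
CPM plus 0.1 (log axis) of the 6 members of the miR-309 cluster and of miR-311-3p, miR-312-3p and miR-986-5p, with 1 point per library coloured by subgenus, in female bodies (left) and embryos (right). miR-286-3p averaged 2.88 and 129 normalised CPM in female bodies of the 2 subgenera, and in embryos 82594 (D. mojavensis), 45266 (D. virilis) and 77960 (Sophophora).

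Libraries resembled each other by body part more than by species. Spearman's rho of log2 CPM across the miRNAs that were read, which are not independent replicates, averaged 0.873 ± 0.0922 (SD) between libraries of the same part from different species and 0.658 ± 0.106 between parts of the same species. The difference of 0.215 over 55 libraries exceeded all 100000 shuffles of the part labels within species, whose highest was 0.0835 (permutation test, p 1e-05, the smallest it can give). It was 0.240 within series M and 0.243 within series V. Libraries of the same species and part correlated at 0.985 (range 0.969 to 0.995, 5 pairs) within a series and at 0.815 (0.620 to 0.911, 13 pairs) across series.

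Reads of 23 to 29 nt, the length of Piwi-interacting RNAs, which silence transposons in gonads, made up 59.6% ± 5.41 (SD) of reads of 18 to 30 nt in embryos, 48.8% ± 8.63 in female bodies and 35.0% ± 5.65 in heads of the same 10 species. Female bodies exceeded heads in 10 of 10 species, by 13.9 points ± 8.93 (SD; exact sign-flip test, p 0.00195, the smallest it allows, adjusted 0.0026 over 4 length comparisons). Within series M the difference was 11.4 points in 5 species, 4 of them positive (exact p 0.188, smallest possible 0.0625). Embryos exceeded heads by 24.6 points ± 7.13, again in 10 of 10 (exact p 0.00195, adjusted 0.0026), by 30.5 in the 4 species of series M (exact p 0.125, the smallest possible) and by 20.4 in the 8 of series V (exact p 0.00781). Female and male bodies of 7 species had 45.2% ± 6.42 and 50.8% ± 7.52, a difference of -5.57 points ± 5.96 that did not pass (exact p 0.0625; higher in females in 2 of 7). It turned to 3.24 in the 2 species of series M (exact p 1, smallest possible 0.5) and to 13.3 (higher in 6 of 7, exact p 0.0313) when distinct sequences replaced reads. The D. simulans female body library, where 2S ribosomal RNA took 24.2% of reads, had the highest share of all female bodies, 70.9%.

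Reads of 21 nt, the length of small interfering RNAs, made up 18.8% ± 5.14 (SD) in heads and 12.2% ± 2.35 in female bodies, and heads were higher in 10 of 10 species by 6.60 points ± 5.43 (exact sign-flip test, p 0.00195, adjusted 0.0026). In series M the difference was 9.53 in 5 of 5 species (exact p 0.0625, the smallest possible). A first base of uridine, usual for Piwi-bound RNAs, began 49.3% ± 4.63 (SD) of distinct 23 to 29 nt sequences in female bodies of series M against 29.3% ± 3.60 in heads (5 of 5 species, exact p 0.0625, the smallest possible), a difference of 20.1 points, and embryos exceeded heads by 16.6 points (4 of 4, exact p 0.125, the smallest possible). Female bodies had 46.7% and male bodies 33.6% in the 2 species of series M with both. In series V, not tested, the share was 48.6% ± 13.6 (SD, n = 8) in embryo and 40.9% ± 10.8 (n = 13) in head libraries. There it was lower in embryos than in heads in D. virilis and D. persimilis, and between the head libraries in D. erecta. In D. ananassae, D. mojavensis, D. sechellia, D. willistoni and D. yakuba of series V it was higher in embryos.

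**Figure D4:**
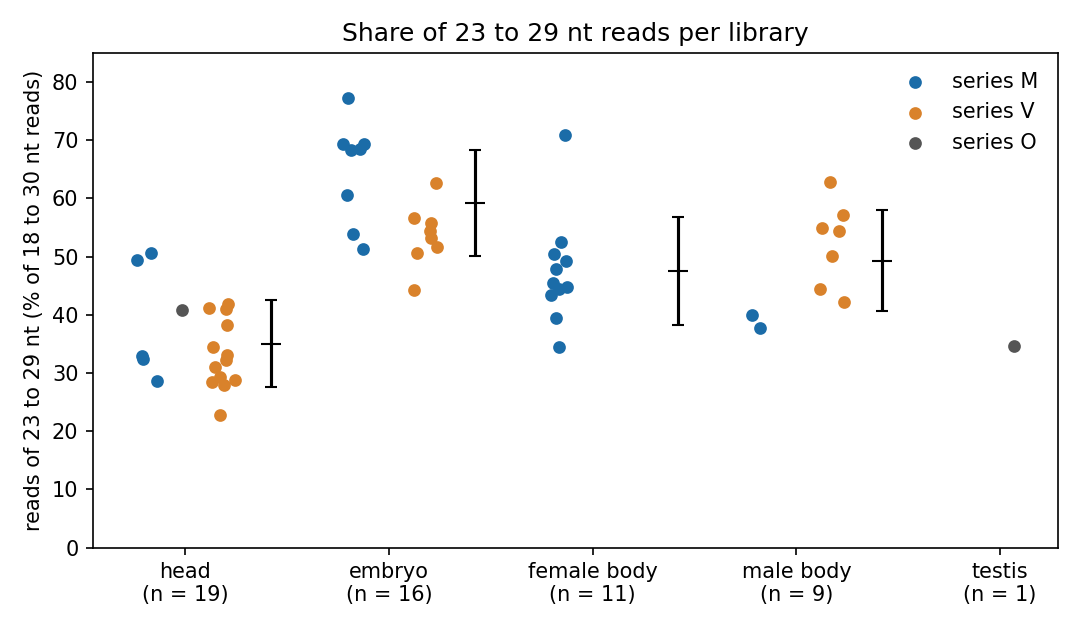
Share of reads of 23 to 29 nt among reads of 18 to 30 nt (percent, vertical axis) in each library of heads (n = 19), embryos (n = 16), female bodies (n = 11), male bodies (n = 9) and testis (n = 1); points are libraries coloured by series letter, and bars are mean and SD of a part. The D. simulans female body stands highest of its part at 70.9%, and the testis library is at 34.7%.

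Read starts of listed miRNAs and other read starts were compared for the number of species that share them. Among 18-base starts that reached 50 reads per 1000000 reads of 20 to 24 nt (RPM) in at least 1 female body, 85 belonged to listed miRNAs and 6784 did not. Of the listed starts, 74 (87.1%) were present at 1 RPM in all 11 species and 0 in 1 species alone. Of the others, 2136 (31.5%) were present in all 11 and 767 (11.3%) in 1. With presence set at 10 RPM the shares in all 11 were 71.8% and 5.11%. The sets differed in level too, and presence depends on it: among starts found in all 11 species the median of the highest level was 2008 RPM for listed and 161 for other starts, and of the others that reached 200 RPM 50.8% were in all 11, against 90.8% of the listed. Starts within 2S ribosomal RNA were left out of the ranking that follows, but not of the counts above. The most abundant unlisted start found in all 11 species averaged 47128 ± 44478 (SD, n = 11) RPM. The next 2, at 11903 and 8312, share 17 bases with it and overlap it. Among starts seen in 1 species the highest were 2 of D. mojavensis, at 1903 and 1016 RPM, and 1 of D. ananassae at 998. D. pseudoobscura had 181 and D. persimilis 170 such starts, D. simulans 6 and D. erecta 0. What these unlisted starts are was not analysed here. Any starts within 2S ribosomal RNA, or of a miRNA changed in sequence, read from another 5 prime end or missing from the list, count among the 6784.

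The testis of D. simulans gave 1 library, so its values carry no test. The testis cluster list, miRNAs of clusters read from testis, took 1.11% of 704956 miRNA reads there (exact 95% interval 1.08 to 1.13, counting error only). That was 205.7 per 1000000 reads of 18 to 30 nt (201 to 210), against 1.64 to 7.51 in the 4 other D. simulans libraries. miR-977-3p led with 3009 reads (4268 CPM), followed by miR-963-5p (1861 reads), miR-976-3p (1158), miR-964-5p (1123) and miR-962-5p (560). Of 18 members 6 were read in the D. simulans libraries. The most abundant miRNAs of the testis were miR-14-3p (22.9%), miR-12-5p (15.2%) and miR-8-3p (8.11%).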

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

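The tests of library series, scaling, changed sequence, embryos inside females and other RNA in the head library, and the comparisons with random splits of the libraries, were chosen after the results they weigh were seen; the test without the D. grimshawi and D. simulans female bodies was chosen after the data were seen but before its own result was. Among male bodies (9 libraries), 30 measures were checked for 1 library far from the rest, and 11 had one. Other parts were not checked. Chance gives this in about 1 in 20 checks only if values are normally distributed. Most of the measures were CPM on a linear scale, which are skewed, so the 11 are not a measured excess.

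D. virilis male body M027, 1 of the 2 male libraries of series M, stood apart in several of these measures, in normalised CPM: miR-281-5p at 366279 (others 5323 to 119278), miR-263a-5p at 167891 (10701 to 46286), miR-31a-5p at 43493 (10199 to 25559), miR-125-5p at 1117 (71.8 to 549) and miR-92a-3p at 302 (2.28 to 21.6). Its miR-310-3p, at 0.815 (0 in all others), is 1 of the 11 only by construction, since it is a single read, the 1 found in male bodies. D. persimilis male body V111 stood apart with miR-987-5p at 2695 (318 to 908) and miR-8-3p at 1735550 (165696 to 566787); a normalised value can pass 1000000 because CPM are divided by a scaling factor, 0.217 in that library. D. grimshawi male body V109 had miR-282-5p at 3273 (54.7 to 387), and D. mojavensis male body V110 had miR-994-5p at 85.4 (0.652 to 35.9). 2S ribosomal RNA took 16.5% of reads in D. willistoni male body V117 (2.77 to 8.95 in the others). The next highest miR-281-5p, 119278, was of M022, the other male library of series M, so that measure follows the series letter. No explanation of the values of these libraries was tested.

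The excess of 21 nt reads in heads over female bodies differed between the subgenera, at 13.3 points in 2 species of subgenus Drosophila and 4.92 in 8 of Sophophora, a difference of 8.40 (exact permutation over 45 splits, p 0.0444). It is 1 of 4 such tests, and the other p-values were 0.711, 0.111 and 0.4, so it does not pass after adjustment for the 4. In data outside the comparisons, the testis cluster list was read in the testis library at 205.7 reads per 1000000 of 18 to 30 nt, against 1.64 to 7.51 in 4 other D. simulans libraries. In the 14 libraries with reads of up to 36 nt, reads outside 18 to 30 nt made up as much as 17.4% (lowest 6.12, median 10.6), and they were left out of the length shares. Those over 30 nt that began with a listed miRNA were counted for it.

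Of 100 splits of the libraries into groups of the real sizes, the real one included, only 1 gave as many called miRNAs as the real split, the real one itself, in each comparison. Random splits thus rarely gave such counts, but 100 splits can show no rate under 1 in 100. They do not weigh the relatedness of species, so they do not settle what the subgenus count rests on. Head against body gave 71 (highest other split 15), embryo against adult 82 (16), female against male body 69 (8) and the subgenus in female bodies 14 (3).

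The miR-309 cluster, lower in 5 members in female bodies of subgenus Drosophila, belongs to embryos. A changed sequence is excluded as the whole cause, since the 5 members reached a median of 0.820 times the Sophophora level (range 0.772 to 1.58) in embryos of D. mojavensis and D. virilis (D. grimshawi embryos are not among the libraries used here). The D. grimshawi and D. simulans libraries are excluded too: without them the median was -5.56 (-6.10 to -4.11). Whether fewer embryos or late eggs were inside these females stays open: 4 other embryo miRNAs that were read in embryos of both subgenera had a median of -1.46, but they ranged from -2.04 to 0.47 and so decide nothing. miR-968-5p, hardly read in this subgenus even in embryos, was left out of them. A difference between the subgenera in ovarian or maternal expression may also underlie the pattern and was not tested.

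Female and male bodies were almost all of different library series, M and V. Within series M alone 47 of 104 miRNAs were called between the sexes, 26 higher and 21 lower in females, which argues against the series as the whole cause. That argument rests on 2 male libraries alone, the shallowest and M027, and both are among the 7 doubted. Their identifiers, M022 and M027, lie below those of all female bodies, M040 to M055. A batch within series M therefore cannot be told apart from sex. Without the doubted libraries 63 were called, and then all males were of series V, so the series term alone separates sex from series there. A scaling error shifts all miRNAs alike. At most 33 of the 69 called lay within 2 standard errors of any 1 common shift (3.61). Only called miRNAs entered this count, chosen for lying far from 0 in either direction, so it could hardly come out high and decides little. Of the calls 66.7% were higher in females and the rest lower, and 1 common shift alone does not move miRNAs both ways. A scaling error stays open as a part of the cause. The setting tried, relative log expression, moved the median by only -0.13 and so decides little. A difference between the sexes stays open as a hypothesis found on the same data. Faults of the 2 male libraries in series M, or a batch within that series, stay open beside it and were not tested apart. The tissue a difference between the sexes would come from was not tested.

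D. simulans head library O002, the only head of series O, had 29.99% 2S ribosomal RNA and 18.3% miRNA reads, against 1.87% and 65.1% in head library M023, and 40.9% against 25.6% of distinct 23 to 29 nt sequences began with uridine. Testis RNA is excluded as the main source, since the testis cluster list reached 3.65% (2.97 to 4.46) of its level in the testis library. A small part is not excluded: the list had 7.51 reads per 1000000 (6.23 to 8.98) in O002 and 1.83 (1.33 to 2.45) in M023. For body RNA in O002 the lists disagree, so it is not excluded. The ovary list had 15.9 reads per 1000000 (14.01 to 17.97) in O002, 3501 in M023 and 5497 in the D. simulans female body. It was also low in the testis library of series O, at 6.96. The muscle list had 5467 (5431 to 5503) in O002, 2375 in M023 and 13623 in the female body. Whether M023 is the head library that holds other RNA was not tested. Its rho of 0.620 with M023 lay below that of the other pairs across series (0.769 to 0.911), and since series O holds no other head, the series and the sample cannot be told apart. No biological explanation was tested.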

How the results depend on the processing

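The alternatives for the lists, those without the doubted libraries, with 2 batches of V, with male bodies for the subgenus and without 2S ribosomal RNA were chosen after the data were seen.

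The counts of called miRNAs stayed within 1.5 times for embryo against adult (63 to 85 over 23 alternatives, 82 as reported) and female against male body (47 to 73 over 22, 69 as reported). For head against body 22 of 23 did (up to 77, 71 as reported), and series M alone gave 39, with fewer libraries; 69 of 70 signs were kept there. Leaving out 1 species gave 67 to 72 for head against body, 76 to 84 for embryo against adult and 64 to 71 for female against male body. Series V alone gave no value for female bodies, since it holds none. Among the named miRNAs, 547 of 552 values under alternatives kept sign and call for head against body, 551 of 552 for embryo against adult and 513 of 528 for female against male body, where 14 lost the call and miR-310-3p turned to -1.40 in series M, having 1 read in male bodies in all. The share of calls that were higher crossed its even point for head against body, where it ran from 37.5% to 55.4% (43.7% as reported, 51.3% in series M), and for embryo against adult, from 41.2% to 55.6% (52.4%). It ran from 14.3% to 50% for the subgenus (21.4%) and from 55.3% to 68.6% for female against male body (66.7%).

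The subgenus count of 14 was the least stable. It was 0 in heads and 0 in male bodies (fewer species, with 3 and 7 miRNAs at an unadjusted p under 0.05 in edgeR, and 0 and 1 called by DESeq2), 4 with 10 reads required in each library (83 miRNAs), 8 without the doubted libraries, and 7 to 16 when 1 species was left out; the lowest came without D. grimshawi or D. virilis, and D. mojavensis gave 9. The highest was 20 with DESeq2. Of 153 named values 47 lost the call, and miR-282-5p turned to -1.10 in heads (the cause was not tested).

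Of the list tests 26 of 43 passed, 17 in series M (15 of them shared), 25 without the doubted libraries and up to 30 with relative log expression scaling. In series M the length differences were 11.4 (female body against head), 30.5 (embryo against head) and 9.53 (21 nt), each in the same direction, with 4 or 5 species and so no p under 0.0625 possible. For female against male bodies the share of 23 to 29 nt turned to 3.24 in series M and to 13.3 with distinct sequences; the cause was not tested. Leaving out 1 species kept each sign: 11.6 to 14.8, 23.3 to 25.9, -7.29 to -4.78, and 5.46 to 7.30 for 21 nt. Profile similarity ran from 0.230 to 0.366, and the testis list was 1.12% with the whole sequence matched.

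The breadth of read starts moved with its limits. Requiring 10 RPM for presence gave 71.8% of listed and 5.11% of other starts in all 11 species and 31.7% of others in 1, as a stricter limit must lower breadth, and requiring 200 RPM in 1 species gave 50.8% and 4.18% of others. Starts of 20 bases gave 89.2% and 30.5% in all 11 and 11.5% of others in 1. In the series M comparison of the sexes 1 of the 2 male libraries held 1220335 reads, and the effect of its depth was not tested.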

Other observations

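The comparison of the 2 read arms of miR-281 and the values of single libraries given here were chosen after the data were seen, and no hypothesis was tested on them.

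The 2 arms of miR-281 moved apart between the sexes: the 5p arm was at -5.85 ± 0.77 for females over males and the 3p arm at 1.43 ± 0.47, while between heads and bodies both were lower in heads, at -2.21 ± 0.51 and -5.51 ± 0.33. Between the library series the arms moved apart too, at -3.96 ± 0.51 (5p) and 1.74 ± 0.32 (3p) for V over M. Females were all of series M and males mostly of V, so both joint values for the sexes depend on the series term. miR-281-5p was at -7.14 within series M and at -2.68 without the series term. In the Hox cluster miR-10-5p and miR-10-3p were both lower in heads and lower in females than in males (-3.02 and -1.81), and miR-iab-4-5p was higher in females at 4.39 ± 0.78 and higher in embryos at 5.45 ± 0.43. miR-315-5p was high in heads and in embryos and lower in females than in males, at -4.22 ± 0.61.

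The number of listed miRNAs at 10 CPM differed by species, from 82 in D. grimshawi, with 2 libraries and no embryo or head, to 101 in D. sechellia (3 libraries) and D. simulans (5 libraries). The D. simulans count includes the only testis library. Of its libraries, that one alone held miR-962-5p, miR-963-5p, miR-964-5p and miR-976-3p at 10 CPM. D. ananassae had 99, D. erecta 97, D. yakuba 96, D. willistoni 95, D. mojavensis, D. persimilis and D. virilis 93 each, and D. pseudoobscura 91. The list is of D. melanogaster, whose nearest relatives here are D. simulans and D. sechellia, so a count per species is also a count of starts kept since their common ancestor, and a wrong entry in the list, which was not checked against a database, lowers the counts of all species.

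In the testis library reads of 23 to 29 nt made up 34.7% and reads of 21 nt 11.9%, and 1.86% of reads were of listed miRNAs. 2S ribosomal RNA reached 29.99% in D. simulans head O002, 24.2% in the D. simulans female body, 19.8% in a D. persimilis embryo library and 16.5% in a D. willistoni male body. Starts seen in 1 species numbered 181 in D. pseudoobscura, 170 in D. persimilis, 101 in D. ananassae, 99 in D. mojavensis, 60 in D. virilis, 56 in D. grimshawi, 52 in D. willistoni, 28 in D. sechellia, 14 in D. yakuba, 6 in D. simulans and 0 in D. erecta. A species with a close relative in the set can share its starts with it, so these counts also reflect which species were sampled.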
